A study of Mus musculus with 6 samples.

How the data were processed

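Gene expression was measured in the hypothalamus of male DBA/1 mice with in-house printed 2-colour oligonucleotide arrays of 10080 spots in 48 printing blocks. Each array set a collagen-injected sample directly against a control sample. The 6 arrays formed 3 biological replicates, each with 2 arrays that carried the dyes in opposite orientation, per the labels. The labels do not say whether one replicate was 1 mouse or a pool, so the p-values measure the spread between these samples. Replicate numbers came from the sample titles, and each array had 3 files, treated as repeat scans and never as replicates. Log ratios of the scans correlated at 0.94 to 0.98 on the arrays of replicates 1 and 2. Scans agreed less in replicate 3, at 0.60 to 0.86 with collagen in Cy5 and 0.72 to 0.75 with collagen in Cy3.

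The deposited spot values were background-subtracted intensities in channels A and B, per the file headers, summed over the pixels of a spot and set to 0 where a channel had been rejected. The spot area in pixels, the local background and a saturation factor, a fraction between 0 and 1, were also taken from the deposited files, per the file headers. The quantification software and the dye of each channel were not given in the sources used here. The deposited value table of the authors held 1 log ratio per probe and array with no stated base. Against log2 ratios of bright spots, smoothed within printing blocks, its slopes were 0.386 to 0.742. These differ too much between arrays to settle the base. The authors' values were read as natural logs, a scale that remains inferred. Column medians of that table lay between -0.018 and 0.0015, so each column was centred near 0. Its direction also remained inferred. The scanner rows were put in the order of the table by block and spot position. With this order the detected spots correlated at a mean of 0.804 with those of the table, against 0.174 for the next best of 384 orders tried.

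Channel A was read as Cy3 and channel B as Cy5, because the labels list Cy3 as the first channel, but this is not stated. With this reading every column of the authors' table correlated positively with the collagen over control ratio of its array, at 0.681 to 0.908. Those ratios were smoothed within printing blocks. The direction of that table is itself inferred, so the sign cannot decide between the readings. If channel A were Cy5, every direction given for collagen against control would be turned.

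Normexp background correction with an offset of 50 had been planned for uncorrected intensities. Because the deposited intensities were already corrected, they were used as they stood, and normexp became an alternative. Log2 ratios of channel B over channel A were taken for spots measured in both channels and smoothed against intensity by loess with a span of 0.3 in each scan. Scans were averaged per spot, leaving out a scan with saturated pixels where another scan had none. Ratios were turned to collagen over control, and the 2 arrays of a replicate were averaged. No background SD was given, so a probe had to exceed 1.5 times the local background in at least 1 channel on at least 4 of 6 arrays. That filter removed 0 of the 2316 probes with a ratio on all 6 arrays. Each mean of the 3 replicates was tested against 0 with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9.

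Of the 10080 probes, 9066 had 1 gene symbol in the platform table, 12 had several and 1002 had none there. Entrez identifiers matched 8977 probes to the mouse RefSeq gene table of assembly GRCm38.p6, used for names only. Control spots were not separated from other spots. Probes of 1 gene were tested apart, and of the 22 genes with several tested probes, 10 had probes of opposite sign.

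A set of 31 gene lists for pathways and cell types was fixed before the data were examined. Lists with at least 5 measured genes were tested with camera at a correlation of 0.01, two-sided, with 1 probe per gene, the brightest. The rule for named genes was also fixed then. It took the 12 largest changes in each direction past the threshold with the same sign on 6 arrays, filled up by the smallest p among tested probes with the same sign on 6 arrays. Members of lists past the threshold and preset genes of hypothalamic, stress and immune function were added.

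On simulated replicates made from these data for collagen against control, with 200 of 2316 probes changed, 62.2% of probes changed 2-fold and 95.5% of those changed 4-fold were found at the adjusted threshold. Of probes changed 1.41-fold, 0.746% were found, with 0 false calls per simulation over 20 simulations. The 200 probes were a mix of these sizes, with the same change added to every replicate and a dye effect that cancelled exactly. These shares hold for that setting. They do not give the power for fewer changed probes, for changes that differ between replicates or for arrays that were not swapped. Alternatives were other background corrections, normalizations, filters, scans, prior variances, a replicate block, single dye orientations, left-out replicates and the authors' table.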

Results

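The arrays compared the hypothalamus of DBA/1 mice, a strain used for collagen-induced arthritis, after injection of type II collagen in complete Freund's adjuvant or of the adjuvant alone. Mice were 8 weeks old. The collagen group received 100 ul of collagen in 100 ul of adjuvant and the control group 200 ul of adjuvant. The volume of adjuvant thus differed as well and cannot be told apart from collagen, so a collagen difference below covers both. Both groups received lipopolysaccharide at day 24. The unit of the later time of killing is unclear in the labels. There were 3 biological replicates, each with 2 arrays that the labels give as a dye swap. Between 4650 and 8562 of the 10080 spots had a ratio on an array, or 46.1% to 84.9%. In the first scan the median foreground per pixel was 880 to 2408 in channel A over a background of 393 to 1353, and 828 to 1213 in channel B over a background of 222 to 489. The number of arrays limits the precision.

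The comparison of collagen with control asked which hypothalamic transcripts differed in mice that the submitters call arthritic, and no measure of arthritis was analysed here. Directions rest on reading channel A as Cy3, which follows the channel order in the labels but is not stated. The authors' table cannot decide it, because the direction of that table was itself inferred. No probe passed the threshold. With limma, 0 of 2316 tested probes had an adjusted p under 0.05, and the smallest adjusted p was 0.872. The test takes the dye swap from the labels, and on arrays that were not swapped, turning and averaging the ratios would cancel a difference between collagen and control. At an unadjusted p under 0.05 there were 25 probes, 14 higher and 11 lower with collagen, where 5% of the tested probes is 115.8. Of simulated unchanged probes with the spread of these replicates, 1.07% reached that p. That split was 12 higher and 41 lower with median centring, 13 higher and 21 lower with print-tip loess, and 16 higher and 6 lower with replicates centred on the tested probes. It was 37 higher and 51 lower without replicate 1, 87 and 14 without replicate 2, and 197 and 9 without replicate 3. It was 97 and 7 with collagen in Cy3 only, 187 and 216 with collagen in Cy5 only, 12 and 20 with a replicate block, and 7 and 21 without the fourth block column. Replicate log ratios hardly correlated across probes, which are not independent, at 0.16 for replicates 1 and 2, -0.12 for 1 and 3, and -0.13 for 2 and 3. The median half-width of the 95% interval of a log2 ratio was 0.45.

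The 4 named genes that were higher with collagen on 6 of 6 arrays did not pass the test. Pnoc (Entrez Gene 18155), the precursor of the opioid-related peptide nociceptin, had a log2 ratio of 1.04 ± 0.38 (SE, n = 3; limma adjusted p = 0.872). Cpn2, a subunit of carboxypeptidase N, stood at 0.97 ± 0.32, Psmd6, a proteasome subunit, at 0.97 ± 0.35, and Ebp, a sterol isomerase of cholesterol synthesis, at 0.59 ± 0.18. All 4 probes lay in the fourth column of printing blocks, where 1 array of replicate 1 had displaced ratios. On that array Pnoc read 4.11, Psmd6 3.77 and Cpn2 3.14, whereas Pnoc read 0.23 to 0.60 on the other 5 arrays. Without replicate 1 Pnoc was at 0.46, Cpn2 at 0.50 and Psmd6 at 0.44, while Ebp, whose highest array was in replicate 2 at 1.27, was at 0.56. With print-tip loess the 4 genes fell between 0.16 and 0.44, Pnoc and Cpn2 being higher on 6 arrays and Ebp and Psmd6 on 4.

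**Figure D1:**
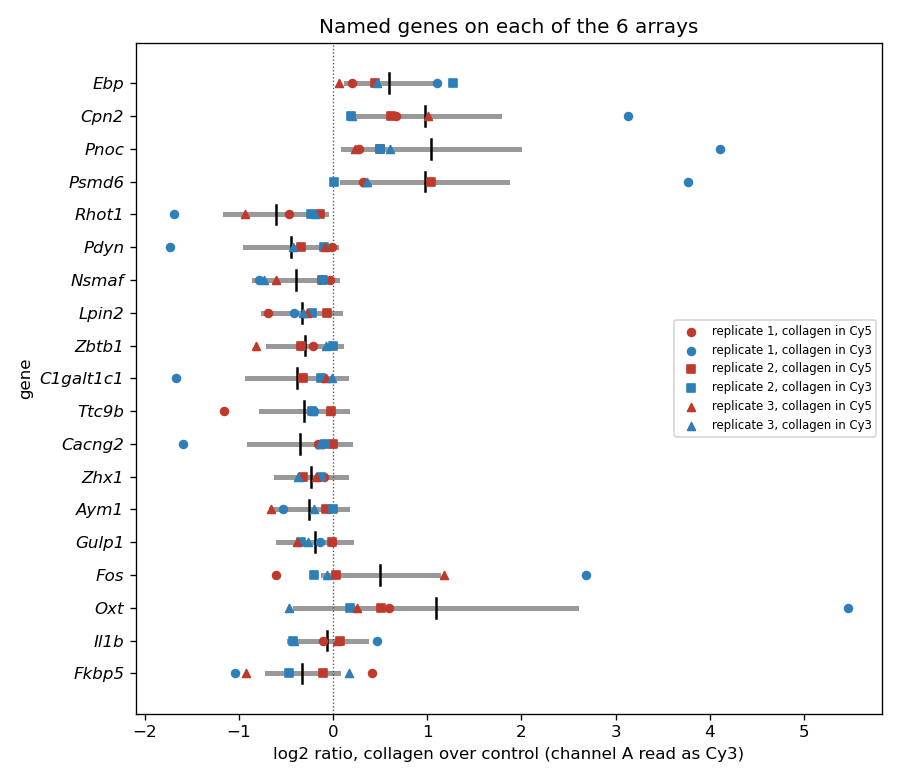
Log2 ratio of collagen over control (horizontal axis) for each named gene (vertical axis) on the 6 arrays, with the mean of 3 replicates as a black tick and its 95% interval as a grey bar. Pnoc at 4.11, Psmd6 at 3.77 and Oxt at 5.47 stand far from their other arrays on the replicate 1 array with collagen in Cy3.

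The 11 named genes that were lower with collagen on 6 of 6 arrays had log2 ratios of -0.61 to -0.19, and none passed the test. Rhot1, a GTPase of mitochondrial transport, was at -0.61 ± 0.22 (SE, n = 3; limma adjusted p = 0.872). Pdyn (Entrez Gene 18610), the dynorphin precursor, was at -0.45 ± 0.20, with replicate values of -0.87, -0.22 and -0.26. Nsmaf, an adaptor in tumour necrosis factor signalling to sphingomyelinase, was at -0.40 ± 0.18, and Cacng2, an auxiliary subunit of AMPA receptors, at -0.36 ± 0.22. Lpin2 was at -0.33 ± 0.17, Zbtb1 at -0.30 ± 0.16 and C1galt1c1 at -0.39 ± 0.21. Ttc9b, Zhx1, Aym1 and Gulp1 lay between -0.31 and -0.19. Over all tested probes, 18 had the same sign on 6 arrays, where independent signs would give 72.4. With print-tip loess 1 of the 11 genes, C1galt1c1, was lower on 6 arrays, and the other 10 were higher on 1 to 3 arrays. Aym1 was then at 0.015, so its direction turned. All of the 11 but Nsmaf lay in block columns 2 or 3. On the replicate 1 array with collagen in Cy3, the blocks of these genes had median ratios of channel B over channel A of 0.25 to 0.86. Turned to collagen over control, such a displacement reads as lower. The block of Nsmaf, in column 1, was at -0.35. Without replicate 1 Cacng2 was at -0.09, C1galt1c1 at -0.14, Ttc9b at -0.13, Pdyn at -0.24 and Rhot1 at -0.38, and without replicate 3 Nsmaf was at -0.26, Aym1 at -0.17 and Gulp1 at -0.13.

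Among the preset genes, Oxt, the oxytocin precursor, had a log2 ratio of 1.09 ± 0.60 (SE, n = 3; limma adjusted p = 0.872) and was higher on 5 of 6 arrays. Its probe lay in the fourth block column, its value rested on 1 array at 5.47, and without replicate 1 it was 0.12. Fos, an immediate early gene, was at 0.50 ± 0.24 and higher on 3 of 6 arrays. It read 2.68 on 1 array of replicate 1, and was at 0.23 without that replicate, at 0.80 without replicate 2 and at 0.14 with median centring. Fkbp5, a glucocorticoid-induced chaperone of steroid receptors, was at -0.33 ± 0.15, with replicate values of -0.32, -0.28 and -0.38. Its single arrays were less even, lower on 4 and higher on 2. Il1b, the cytokine interleukin 1 beta, was at -0.06 ± 0.17 and changed sign with several settings. The probes of Avp, Trh, Sst and Il6 had ratios on 3, 2, 2 and 1 arrays and were not tested. No named probe of Crh, Pomc, Npy, Agrp, Nr3c1 or Tnf was found in the table used here.

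Of the 9 gene lists with at least 5 measured genes, 0 passed camera, and the smallest adjusted p was 0.365. With an estimated correlation every list had adjusted p = 0.941, and with fry the smallest was 0.326. In each of the 9 lists, 0 members passed the threshold over all probes and 0 passed adjusted over the list alone. At an unadjusted p under 0.05 each list also had 0 members. Of the 135 measured genes of all lists, 69 changed sign when 1 of the replicates was left out, 55 of them without replicate 1. The counts of positive and negative members thus depend on single replicates. The median log2 ratio over all tested probes was -0.09, with -0.21 in replicate 1, -0.01 in replicate 2 and -0.0094 in replicate 3. Counts and medians of the lists are to be read against this offset. Camera compares a list with the other genes, so its direction can be up where the median is negative.

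Of 8 measured hypothalamic neuropeptide genes, 2 had positive and 6 negative log2 ratios (median -0.19, mean 0.09; camera adjusted p = 0.912, direction down). Gal, the galanin precursor, was at -0.26 ± 0.16, Gnrh1 at -0.20 ± 0.15 and Pmch, which encodes melanin-concentrating hormone, at -0.07 ± 0.15. Tac1, the substance P precursor, was at 1.01 ± 0.48, with replicate values of 2.56, 0.16 and 0.31. Of 6 stress axis genes, 2 were positive and 4 negative (median -0.12; camera adjusted p = 0.912). Crhr1, a receptor of corticotropin-releasing hormone, was at 0.04 ± 0.16, and Hsd11b2, which inactivates glucocorticoids, at 0.80 ± 0.42. Tac1 and Hsd11b2 lay in the fourth block column, and the replicate values of Hsd11b2 were 2.11, 0.34 and -0.05. The 6 glucocorticoid-induced genes had a median of -0.08 (camera adjusted p = 0.912), with Klf9 at 0.17 ± 0.17 and Mt1 at -0.09 ± 0.21. Without replicate 1 Mt1 turned to 0.15 and Crhr1 was at 0.0023, and without replicate 3 Klf9 was at 0.07.

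The inflammation list had 9 measured genes, 4 positive and 5 negative (median -0.04, mean 0.11; camera adjusted p = 0.365, direction up). Saa3, an acute-phase protein, was at 0.79 ± 0.46 and Ccl3 at 0.40 ± 0.21, against Vcam1 at -0.22 ± 0.27 and Lcn2 at -0.08 ± 0.21. Saa3 and Ccl3 lay in the fourth block column, and Saa3 had replicate values of 2.18, 0.48 and -0.28. With print-tip loess Ccl3 was at 0.0086, Saa3 at 0.24 and Vcam1 at -0.02. Without replicate 1 Vcam1 turned to 0.14, and Ccl3 was at 0.14 and Saa3 at 0.10, and without replicate 3 Lcn2 turned to 0.11. The 8 heat shock genes had a median of -0.12, with 2 positive and 6 negative (camera adjusted p = 0.833), and Hsp90aa1 was at -0.35 ± 0.24, or -0.07 without replicate 1. With array quality weights, chosen after seeing the data, camera gave an adjusted p of 0.0087 for the inflammation list (direction up) and 0.0024 for the heat shock list (direction down). Replicate 2 had a weight of 4.83, against 0.21 and 0.97 for replicates 1 and 3. That setting thus rests mainly on replicate 2 and does not show agreement between replicates.

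Of 21 oxidative phosphorylation genes, 13 were positive and 8 negative (median 0.04; camera adjusted p = 0.365). Of 22 ribosomal protein genes, 7 were positive and 15 negative (median -0.11, direction up in camera; adjusted p = 0.912). Without replicate 1, this list alone was past the threshold among 13 tested, with a median of 0.12 and a camera adjusted p of 0.0166. Array quality weights put 4 lists past it, the inflammation and heat shock lists, the ribosomal one at a camera adjusted p of 7.01e-05 and oxidative phosphorylation at 0.0024 (both with direction up in camera). The weights were 0.21, 4.83 and 0.97 for replicates 1, 2 and 3, so these 4 results rest mainly on replicate 2.

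The 11 synaptic vesicle genes had a median of 0.03 and a mean of -0.0071 (camera adjusted p = 0.833, direction up). Cplx1, a regulator of vesicle fusion, was at 0.37 ± 0.15, with replicate values of 0.48, 0.32 and 0.32. Its single arrays were less even, and it was higher on 4 of 6. The neuron list, the only cell type list with enough measured genes, had 6, with 2 positive and 4 negative (median -0.06; camera adjusted p = 0.912). Oligodendrocyte markers had 4 measured genes, with Cldn11 at 0.39 ± 0.18 and Mag at -0.27 ± 0.25, the latter from replicate values of -0.94, 0.10 and 0.03. Astrocytes had 2, with Aldh1l1 at -0.09 ± 0.19 and Ndrg2 at -0.02 ± 0.17. Without replicate 1 Aldh1l1 turned to 0.10 and Ndrg2 to 0.08. Microglia and macrophages had 1, Cd68, at -0.03 ± 0.15. The lists of T cells, B cells, erythrocytes and interferon-stimulated genes had 0 measured genes.

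Of the lists with 1 to 4 measured genes, ependyma and tanycytes had Gpr50, Lhx2 and Rarres2 between -0.23 and -0.15, and choroid plexus had Kl at -0.30 ± 0.17. Pituitary markers Scg2 and Pitx1 stood at -0.23 ± 0.15 and 0.25 ± 0.19. Without replicate 1 Rarres2 was at -0.02, Gpr50 and Lhx2 at -0.09 and Pitx1 at 0.05. Endothelium had medians of -0.04 over 2 genes, granulocytes 0.06 over 2, striatum 0.05 over 4 and thalamus and cortex -0.15 over 4. Immediate early genes had a median of -0.08 over 4, antigen presentation -0.31 over 2 and complement -0.11 over 1. Monoamine genes had a median of -0.03 over 4, GABA and glutamate genes 0.02 over 4 and energy balance genes -0.19 over 4. The opioid and nociception genes went both ways, with Pnoc at 1.04 and Tac1 at 1.01, both in the fourth block column, against Oprd1 at -0.22 and Pdyn at -0.45. The clock genes were Csnk1e at 0.88, also in the fourth block column and with replicate values of 2.28, -0.0047 and 0.36, and Dbp at -0.03. Without replicate 1 Dbp turned to 0.29 and Oprd1 was at -0.07. In the thalamus and cortex list Calb2, Neurod6 and Fezf2 then turned to 0.09, 0.10 and 0.07, while Ntng1 was at -0.26. Canx of the antigen presentation genes turned to 0.13, with Calr at -0.16. Of the immediate early genes Dusp1 turned to 0.19, and Fos, Fosb and Jund kept their signs. The medians of these lists thus depend on replicate 1.

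No probe was detected in collagen on 6 arrays and in control on 0, or the reverse. Get4, Cyp46a1, Siah2 and Izumo1r were detected in collagen on 6 arrays and in control on 3, and Ccdc105, Pgam5 and Rbm22 in collagen on 3 and in control on 6. Detection on at least 5 arrays in collagen and at most 2 in control was seen for 6 probes, and the reverse for 22. In the first scan 2743 to 6211 spots per array were rejected in channel B and 665 to 2115 in channel A. Detection thus differed by channel and array, and the counts cannot be read as transcripts gained or lost with collagen. The named genes were chosen after their values were seen, and the detection differences between collagen and control were not tested.

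**Figure D2:**
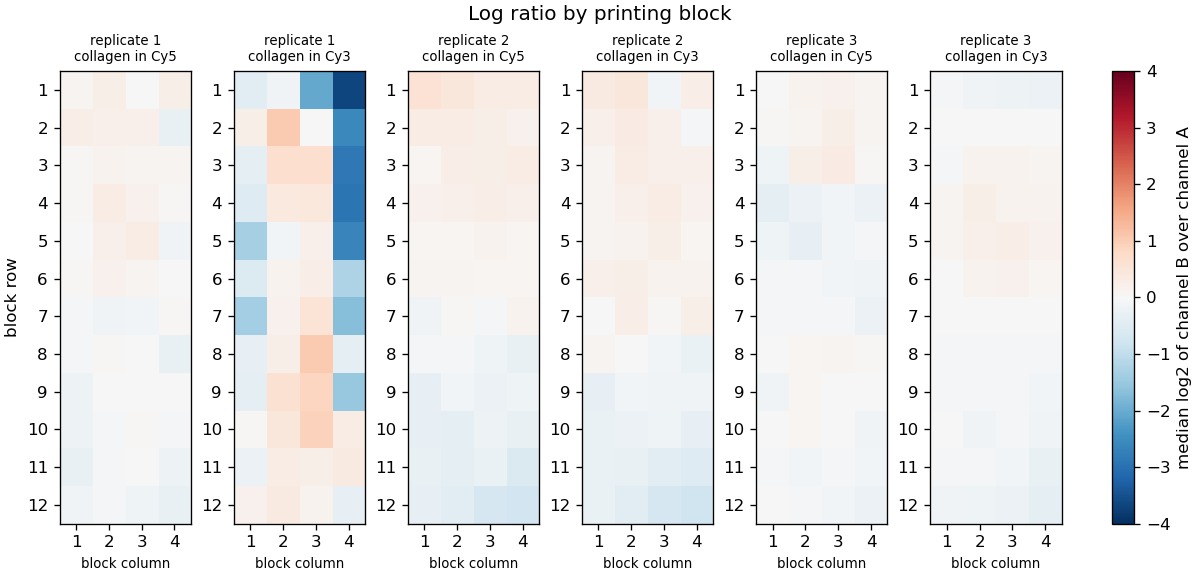
Median log2 ratio of channel B over channel A (colour) in each printing block, by block row and block column, for the 6 arrays. On the replicate 1 array with collagen in Cy3 the upper 8 rows of the fourth column lie 2.56 below the rest, while the other arrays differ there by -0.02 to 0.16.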

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

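The tests of an edge signal, of a collagen effect and of the SD that remained were chosen after their results had been seen at least in part, and the percent fall without saturated pixels before its result. For 3 of 4 array measures and 8 of 19 named genes, 1 array stood apart from the other 5 by more than the gap rule for 6 values allows. Chance does so in about 1 in 20 groups of independent values with a common spread. That rate cannot be applied here, because the arrays were paired, 1 array had a wider spread and most named genes were picked by these values. The spread of log2 ratios was 1.66 (SD) on the replicate 1 array with collagen in Cy3, and 0.38 to 0.67 on the others. Its channel A background per pixel was 1353, the highest. The replicate 3 array with collagen in Cy3 had the most spots with both channels, 8562, against 5940 on the next. Of the 8 genes, 7 had their extreme value on the same replicate 1 array. They were Oxt at 5.47, Pnoc at 4.11, Psmd6 at 3.77, Cpn2 at 3.14, Pdyn at -1.73, C1galt1c1 at -1.67 and Cacng2 at -1.60. Ttc9b was extreme at -1.15 on the other replicate 1 array.

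On that array the median log2 ratio of channel B over channel A was lower in the upper 8 rows of the fourth block column than elsewhere, by a difference of -2.56, and channel A background was 4327 per pixel against 1229. The turned ratios of 655 edge probes correlated at -0.127 with the other array of the same replicate. The 95% interval was -0.20 to -0.05, with neighbouring spots treated as independent. This value cannot decide on a collagen effect with the dyes as labelled, because a channel ratio shared by the arrays pulls it down. Over the tested probes the dye-swapped pairs of replicates 1, 2 and 3 gave -0.20, -0.75 and -0.32. On the other arrays the same edge blocks differed from the rest by -0.02 to 0.16. The edge is argued against as the whole cause of the wide ratios, since the SD outside it was 1.32, against 0.39 to 0.68 on the other arrays, and smoothing within blocks left 1.14, against 0.34 to 0.57. Saturated pixels are argued against as the whole cause too, since leaving out 706 spots with them lowered the SD by 11.6%, to 1.47. Both may account for part of the spread, and what widened the ratios elsewhere on this array stays open.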

How the results depend on the processing

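Normexp at offset 50 had been planned as the main background correction, and it became an alternative once the deposited values were seen to be corrected. Array weights, the left-out block column, replicate centring, named probes only and 2 replicates were chosen after seeing the data. Of 26 settings, 25 kept 0 probes past the adjusted threshold. The exception was collagen in Cy5 only, with 27 probes (1 higher, 26 lower), of which 20 of the 22 measured on all 3 opposite arrays had the same sign of channel B over channel A there. The replicate block gave 0 probes past the threshold and 32 at an unadjusted p under 0.05, with a correlation within replicates of -0.29, and changed no call. The 25 probes at an unadjusted p became 8 with no background subtraction, 47 and 54 with normexp at offsets 50 and 10, 53 with median centring, 67 with arrays scaled, 11 with both channels above background, 6 with scan file 3, 0 with an intensity trend and robust prior, 15 in the authors' table, 59 with at least 2 replicates and 159 with array weights. Some of these settings tested other numbers of probes, so their counts are not directly comparable with 25. There 5% of the tested probes is 58.4 with both channels above background, 56.5 with scan file 3, 76.95 in the authors' table and 201.05 with at least 2 replicates. In the rest it is 115.8. The 25 probes became 403 with collagen in Cy5 only, where 5% of the tested probes is 141.6, and 104 with collagen in Cy3 only, where it is 170.2. Without 1 replicate they were 88 to 206: 88 without replicate 1, 101 without replicate 2 and 206 without replicate 3, where 5% is 143.5, 124.1 and 165.1. Of 16 settings of the lists, 14 kept 0 lists. Array weights gave 4, and leaving out 1 replicate gave 0 to 1. Il1b turned to 0.014 and 0.035 with normexp at offsets 50 and 10, 0.039 with print-tip loess, 0.0014 with collagen in Cy5 only and 0.017 with centred replicates, and lay between -0.18 and 0.0028 without 1 replicate. Aym1 turned to 0.015 with print-tip loess. The other 17 named genes kept their sign in the 21 to 25 settings that gave each a value, and Pnoc, Cpn2, Psmd6, Ebp and Oxt had none without the fourth block column. The cause was not tested. The test was limited to the 2316 probes with a ratio on all 6 arrays, of which the filter on signal over background removed 0.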

Other observations

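The tests of the missing transcripts and of the shared channel ratio were chosen after these patterns had been seen, and the count over sign patterns before its result. Pmch and Gal were detected in channel B on all 4 arrays of replicates 1 and 2 and on both of replicate 3, and Hcrt on 1 of those 4 and on both of replicate 3. The probes of Snap25, Pcsk1n, Mt3 and Uchl1, abundant in neurons or astrocytes, were detected on both replicate 3 arrays and on 0 of the other 4, as were 2 of 3 Gapdh probes. These genes were chosen after their values were seen. Of 3698 probes detected in both channels on both replicate 3 arrays, 1317 were rejected in channel B on all 4 others. They included 4 of 14 hypothalamic neuropeptide, 6 of 8 astrocyte, 6 of 13 neuron, 10 of 38 oxidative phosphorylation and 12 of 35 ribosomal probes, which kept these out of the comparison.

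Weaker signal on those 4 arrays is argued against as the whole cause, because 27.9% of the 1009 brightest probes of replicate 3 were missing there. Mice that lack the transcripts are argued against as well, because in 50% of 34 such genes (95% interval 32.4% to 67.6%) another probe was detected on all 4 arrays, although probes of 1 gene can differ in sensitivity. Spots that failed to print on those slides are a candidate explanation. The missing share varied over positions within blocks 1.70 times as much as in the most uneven of 100 random placements. Over blocks it varied 8.95 times as much, from 0% to 76.9%, which failed printing and poor hybridisation of regions could both give. The median channel A signal of the missing probes was also low, at percentiles of 22.4 to 34.6 against 71.8 to 88.9 for probes kept. Poor hybridisation in the same places stays open, and channel A was still detected for 65.5% to 94.3% of the missing probes.

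The ratio of channel B over channel A was shared by the arrays whichever channel held collagen. Arrays of opposite orientation and different replicates correlated at a mean of 0.334 across probes, and those of the same orientation at 0.304. A collagen effect alone, with the dyes as labelled, would make the first value negative, so it is argued against as the source of the shared ratio. Added to a shared channel ratio, a collagen effect would only lower the first value, so the sign cannot exclude one. Printing blocks are argued against, since smoothing within blocks left the first value at 0.362. A probe-specific dye bias may account for it, and so could dyes that were not swapped, which these data leave open: in 1 of 3 replicates the 2 arrays correlated more with each other than with any other array.

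A channel difference over the 6 arrays passed the limma threshold for 10 probes, all higher in channel A, including Krt14 at -3.02 ± 0.25, Chst13 at -2.76 ± 0.25 and Kdm5d at -2.51 ± 0.24 (log2 of channel B over channel A, SE). It can be read as a dye difference only if the dyes were swapped as labelled. The 3 replicates have 4 sign patterns, too few for a share under 0.05. The labelled pattern gave 25 probes at an unadjusted p under 0.05, as many or more came from 4 of the 4 patterns including itself, and the highest of the others was 61.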
